A study of Danio rerio with 10 samples.

How the data were processed

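Total RNA depleted of ribosomal RNA was sequenced from gata1-positive cells of zebrafish embryos with a stranded library kit, per the labels' protocols. Per the submitters' processing notes, the tools used were Trim Galore, STAR 2.4.2a, Picard and Cufflinks 2.2.1 on the GRCz10 build, and whether counting used strand is not given in the sources used here. The deposited values are FPKM per gene and library, per the file headers, that is fragments scaled by transcript length and library total, so they hold no counts. The single table of the series has 32233 rows for 32103 gene IDs; 130 rows repeat an ID and were kept as separate rows, and 955 rows have no symbol. All per-sample columns matched a sample title. Positions are those of the table with 1 base added to the start, after which 37 of 37 mitochondrial genes matched the start in the reference gene table. Exon, intron and splice-junction values are not analysed here.

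Libraries were grouped by their titles into 5 sf3b1 mutant and 5 sibling samples. The title of sibling 2 says wild type while its genotype tag says mutant. It was kept as a sibling because the design text gives 5 libraries per group, and an alternative counts it as a mutant. FPKM sums per library ran from 293816 (mutant 1) to 422870 (sibling 5). Absolute depth is unknown. Low values of the same gene fell at whole-read ratios between libraries in 37.7 to 50.2% of cases, which gave each library's depth relative to mutant 1. Exact zeros can be failed estimates, since 24 rows with a mean of at least 100 FPKM are listed at 0 in some libraries, so rows at 0 are given per library without a fold. On the first principal component (27.1% of the variance) sibling 2 lay at 23.8, the other siblings at 27.2 to 40.5 and the mutants at -34.2 to -30.4. On the second (17.2%) mutant 1 and sibling 2 stood apart, at 50.9 and 45.5.

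The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1) for genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and SDs are of FPKM. sf3b1 was also tested with a two-sided exact permutation test. Gene lists, written before the data were examined, were tested with camera (preset correlation 0.01, lists with at least 3 tested members, Benjamini-Hochberg over lists). Of 1023 listed symbols 955 matched by the symbol in the table, 27 by the current symbol of the gene ID and 37 not at all, while 4 repeated another. There were 35 lists, of which the hatching gland list had too few tested members. Some genes sit in more than 1 list. Called genes on chromosome 9 were compared with those elsewhere by a one-sided Fisher exact test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

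Named genes follow a rule fixed before the data were examined: sf3b1; the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group, ranges that do not overlap and a symbol that is not a clone name; the 4 members with the smallest p in each list; and members of the globin, heme, erythroid transcription factor and TGF-beta lists. Not every gene the rule allows is printed, and 1 gene and 1 list that contains it are not reported here. Exceptions are said to have been chosen after their values were seen.

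The alternatives planned before the data were examined were log2(FPKM + 0.1) and log2(FPKM + 5), no filter and a mean of at least 5 FPKM, median of ratios scaling, quantile normalization, an equal sum without globin, mitochondrial and rRNA genes, limma without the trend and with array weights, sibling 2 counted as mutant, the replicate number as a block, each library left out, camera with an estimated correlation and fry. Chosen after seeing the data were leaving out mutant 1 and sibling 2 together, leaving out small noncoding RNA rows, and an exact permutation test of each list's library means. The correlation of list means with epidermal means, on deviations from the group means with an exact permutation within groups and p-values not adjusted over lists, and the linear model of list means with the epidermal mean added were also chosen then.

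The limma step was tested on simulated data for the mutant against sibling comparison, with the real gene means and spreads and 200 genes changed among 12953 run. It recovered 16% of genes changed 1.5-fold, 54% at 2-fold, 86% at 3-fold and 94% at 4-fold, 50 genes each, and called 10 unchanged genes. With no gene changed it called 0 of 12946 genes and 0 lists, and a list with every member shifted was called while 0 other lists were. The simulated genes were independent, so this does not test how correlation between genes affects camera. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1.5, so low genes were left out. They also were a smaller share than the 14.3% called in the real data. The recovery rates are therefore not the power of the real comparison.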

Results

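Gene expression was measured by RNA sequencing in erythroid cells of zebrafish embryos at 24 hours post fertilization. The cells were sorted for gata1, a transcription factor gene that marks the erythroid lineage, from embryos mutant for sf3b1 and from their siblings. sf3b1 encodes a core subunit of the SF3b complex, which recognises the branch point of introns as part of the U2 small nuclear ribonucleoprotein. There were 5 mutant libraries (replicates 1, 3, 4, 5 and 6) and 5 sibling libraries (replicates 2 to 6), and the values are FPKM for 32233 table rows. Read totals are not used here because the values carry no counts. From the step sizes of low values, the depth relative to mutant 1 was 0.57 in mutant 3, the lowest, and 1.26 in sibling 6, the highest, provided that no later scaling was applied. Rows above 0 numbered from 20247 in mutant 3 to 21595 in sibling 4. The labels do not say whether libraries came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

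The transcript of the mutated gene was lower in every mutant library than in every sibling library. sf3b1 (ENSDARG00000056138, GRCz10 chromosome 9, 32350877 to 32366371) had a mean of 19.0 ± 2.17 FPKM (SD, n = 5) in mutants and 40.2 ± 3.24 FPKM (SD, n = 5) in siblings. The mutant libraries lay at 17.6, 16.0, 20.6, 19.4 and 21.3 FPKM and the sibling libraries at 41.0, 36.3, 42.3, 37.5 and 43.9 FPKM. The log2 fold change of FPKM + 1 was -1.05 (SE 0.13, limma adjusted p = 3.26e-04), and the two-sided exact permutation p was 0.0079, the smallest that 252 relabellings can give. Sibling 2, whose genotype tag disagrees with its title, had 41.0 FPKM of sf3b1, within the range of the other siblings and above every mutant.

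The comparison of mutant with sibling cells asks how loss of this splicing factor changes the transcripts of early red blood cells. With its preset correlation camera called the 2 lists of the splicing machinery higher in mutants and those of cell division, replication-dependent histones, heme synthesis and myeloid markers lower. With an estimated correlation adjusted p = 0.0754 for both splicing lists and 0.445 to 0.698 for the others, so none kept its call. Fry and the exact permutation of library means each called these lists except heme synthesis (fry adjusted p = 0.155, permutation adjusted p = 0.152). Of 13003 genes tested with limma, 727 rose and 1137 fell at an adjusted p under 0.05, together 14.3% of the genes. Changes of at least 2-fold on the log2(FPKM + 1) scale were seen for 232 of the rising and 446 of the falling genes. The ranges of the groups did not overlap for 12.2% of tested genes, against 0.79% by chance. After quantile normalization 987 genes rose and 1008 fell, so the excess of falling genes depends on the scaling. Without sibling 4 the falling genes numbered 741, and with sibling 2 counted as a mutant 300 genes rose and 461 fell. With sibling 2 so counted, 39 of the 91 genes named here as past the threshold lost their calls, among them il1b, col1a1b and tgfb1b.

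The largest rises by the fixed rule included prpf31, frg1 and snapc4. prpf31 (ENSDARG00000095904, chromosome 16, 32128329 to 32136642), a component of the U4/U6.U5 particle of the spliceosome, was at 25.1 ± 5.80 FPKM (SD, n = 5) in mutants and 3.09 ± 0.79 in siblings (log2 fold change 2.67, limma adjusted p = 7.78e-06). frg1, a gene linked to pre-mRNA splicing, rose to 48.4 from 7.54 FPKM, and snapc4, a subunit of the complex that starts small nuclear RNA transcription, to 25.2 from 4.08 FPKM. supt7l, a subunit of SAGA-type coactivator complexes, rose by 2.29 on the log2 scale. Also among them, apoeb (an apolipoprotein), isg15 (a ubiquitin-like modifier), lnx1 (a ubiquitin ligase), cpn1 (a carboxypeptidase) and ftr34 (a TRIM family gene) had log2 fold changes of 2.46, 2.41, 2.82, 2.96 and 2.64. A second cpn1 row is not part of that value, which belongs to ENSDARG00000096720.

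The largest falls by the fixed rule included the myeloid markers mpx and lyz. mpx (ENSDARG00000019521, chromosome 10, 7815556 to 7827254), the neutrophil myeloperoxidase, was at 4.76 ± 1.87 FPKM (SD, n = 5) in mutants and 56.7 ± 35.4 in siblings (log2 fold change -3.20, limma adjusted p = 1.57e-04). npsn, a neutrophil metalloprotease, lyz, a lysozyme, and il1b, an inflammatory cytokine, had log2 fold changes of -2.91, -2.80 and -2.28. mrc1a, a mannose receptor, was at 4.52 FPKM in mutants and 27.06 in siblings, and col1a1b, a collagen chain, at 5.55 and 33.2 FPKM. f5 (coagulation factor V), abcb9 (a peptide transporter), pabpc1b (a poly(A)-binding protein) and cx32.2 (a connexin) fell by 2.32, 2.22, 2.08 and 2.07 on the log2 scale. f5 lies on chromosome 9, at 34317821 to 34338811, within 10 Mb of sf3b1, so linkage to the mutated gene is not excluded for its fall. One of 7 rows named MFAP4 (1 of many), ENSDARG00000088745, fell by 2.11, and its reads may be split with near-identical copies.

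Some small noncoding RNA rows had large log2 fold changes in either direction, and their reads are shared among near-identical copies, so they are uncertain. One SNORA3 row, ENSDARG00000104594, was listed at 0 in all 5 mutant libraries and at 96.6, 59.3, 91.2, 47.8 and 36.9 FPKM in the siblings. A different SNORA3 row, ENSDARG00000102089, had means of 84.9 and 85.1 FPKM in mutants and siblings and was picked after its values were seen. For U4, the small nuclear RNA that pairs with U6, the row ENSDARG00000087328 lay at 171.5, 140.1, 135.5, 269.3 and 233.2 FPKM in mutants and 88.7, 28.6, 9.42, 120.5 and 4.86 FPKM in siblings (limma adjusted p = 0.0287). Its call ended without mutant 5, mutant 6, sibling 3 or sibling 4, at adjusted p of 0.0628, 0.0598, 0.0517 and 0.0700. The U4 row ENSDARG00000083431 (adjusted p = 0.0341) was listed at 0 in sibling 3 and sibling 5 and lost its call without any of mutants 1, 3, 4, 5 and 6 or siblings 3 and 5, at 0.0524 to 0.0736. Both calls also ended with no filter on low values, at 0.0698 and 0.0802, and that of the second row on log2(FPKM + 0.1) (0.0640).

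**Figure D1:**
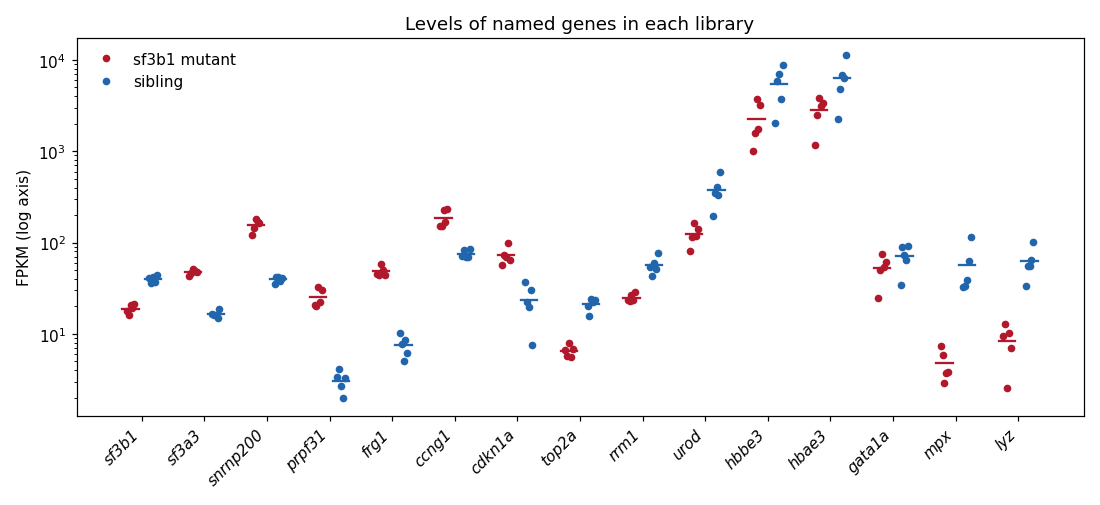
FPKM (log axis) of 15 genes in the 5 mutant (red) and 5 sibling (blue) libraries; each point is 1 library and each bar the mean of its group. sf3b1 was lower in every mutant than in every sibling, and prpf31 and frg1 were higher in every mutant than in every sibling.

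Many spliceosome genes were higher in mutants, but their list calls ended with an estimated correlation. Among 64 tested genes of the wider spliceosome 31 rose and 0 fell (36 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.59. The strongest were dhx16, a helicase of spliceosome activation, at 35.5 ± 3.73 against 6.59 ± 0.52 FPKM (SD, n = 5), snrpd2, a core Sm protein, at 346.5 ± 27.4 against 95.2 ± 8.50, and snrnp200, the U5 helicase, at 155.5 ± 23.1 against 39.7 ± 3.05. The camera adjusted p was 7.14e-20 with the preset correlation, and adjusted p = 0.0754 with an estimated correlation. In the list of SF3b and U2 subunits 11 of 23 rose and 1 fell, which was sf3b1 itself (14 and 2 adjusted over the list alone). sf3a3, sf3a2, sf3a1 and sf3b4, partners of sf3b1 in the U2 particle, rose by 1.46, 1.51, 1.38 and 1.27 on the log2 scale, and the list had a camera adjusted p = 8.01e-08, and adjusted p = 0.0754 with an estimated correlation. In mutants, every library mean of both lists lay above every sibling mean, with an unadjusted exact permutation p of 0.0079 each (0.0385 adjusted over lists). Within groups these means had correlations of -0.42 and -0.18 with those of epidermal markers (p = 0.324 and 0.638).

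Genes that restrain division or act in cell death went both ways. Among 20 genes that brake the cell cycle 5 rose, including rbl2 (5.49 against 1.53 FPKM), ccng1, a cyclin (186.2 against 75.5 FPKM), and cdkn1a, the p21 cyclin-dependent kinase inhibitor (72.8 against 23.2 FPKM), and 2 fell, including rb1 (6 and 3 adjusted over the list alone); the camera adjusted p was 0.124, and the list was called higher without sibling 2 (0.0369), with it counted as a mutant (0.0068) and without both mutant 1 and sibling 2 (0.0455). Within groups its library means had a correlation of 0.77 with those of epidermal markers (p = 0.0056). Among 21 apoptosis genes 4 rose (casp8, bbc3, diablob and baxa) and 1 fell (5 and 2 adjusted over the list alone), with a camera adjusted p of 0.123. The call of baxa ended with the replicate block (0.0617). The gene that fell, pmaip1, which encodes the apoptosis inducer Noxa, did so by 1.15 on the log2 scale and was named after its values were seen.

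Many genes of G2 and mitosis and some of DNA replication fell, while the list calls depended on the correlation used. Of 37 tested genes of G2 and mitosis 23 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 fold change of -0.65. top2a, a DNA topoisomerase, was at 6.53 ± 0.95 against 21.2 ± 3.41 FPKM (SD, n = 5), ube2c (ENSDARG00000035770), which works with the anaphase-promoting complex, at 5.78 against 17.5 FPKM, and cenpf and ttk, kinetochore genes, fell by 1.07 and 1.26 on the log2 scale. Of 43 genes of DNA replication 13 fell and 0 rose (23 and 0 adjusted over the list alone), among them the ribonucleotide reductase genes rrm1 (25.03 against 57.1 FPKM) and rrm2 (ENSDARG00000078069, 3.42 against 13.1 FPKM), rfc1 and chaf1a. Of 12 replication-dependent histone rows 8 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -1.05. Histone genes are near-identical copies, so single rows such as zgc:153405 (34.3 against 109.6 FPKM) are uncertain. Camera adjusted p-values were 3.64e-10, 4.30e-09 and 3.58e-06, and adjusted p = 0.445, 0.461 and 0.445 with an estimated correlation. With fry the adjusted p-values were 0.0060, 0.0146 and 0.0082, and by exact permutation of library means 0.0385 each. Within groups, library means of the G2, replication and histone lists had correlations of -0.71, -0.86 and -0.70 with those of epidermal markers (exact permutation p = 0.0308, 0.0031 and 0.0540). With the epidermal mean in the model the group differences were -0.54, -0.43 and -0.84 (SE 0.11, 0.10 and 0.22), against -0.66, -0.60 and -1.07 without it.

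In the main camera test the heme, globin and red cell membrane lists were called lower, and erythroid transcription factors and iron genes were not called. Transcripts of 4 of 18 heme synthesis genes fell and 0 rose (4 and 0 adjusted over the list alone): alad, urod, ppox and tmem14ca. urod, which removes carboxyl groups from uroporphyrinogen, was at 123.6 ± 31.8 against 375.3 ± 146.4 FPKM (SD, n = 5) and alad, which forms porphobilinogen, at 18.4 ± 5.41 against 73.7 ± 35.2. alas2, the first erythroid enzyme of the pathway, was at 68.9 ± 24.3 and 106.5 ± 49.98 FPKM (adjusted p = 0.366) and cpox at 640.8 and 468.4 FPKM (adjusted p = 0.307). The list had a camera adjusted p = 0.0330, and adjusted p = 0.698 with an estimated correlation; its call ended without mutant 1, mutant 3, sibling 3 or sibling 6, at 0.149, 0.0522, 0.0991 and 0.102, and at a mean of at least 5 FPKM (0.0583). Its median of -0.37 was -0.60 without sibling 2.

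Globin genes, which share reads between paralogs and are uncertain, were called lower as a list at a camera adjusted p = 0.0192, and adjusted p = 0.698 with an estimated correlation; the call ended without mutant 1 or sibling 6, at 0.0810 and 0.0715. In the single-gene test 1 of 11 rows fell and 0 rose (6 and 0 adjusted over the list alone). That row, an embryonic alpha globin (ENSDARG00000089124), was at 58.7 ± 25.4 against 222.8 ± 119.1 FPKM (SD, n = 5, adjusted p = 0.0202), and its call ended without sibling 4 (adjusted p = 0.0520) or with no filter on low values (0.0511). hbae3 was at 2804 ± 1029 against 6306 ± 3311 FPKM (adjusted p = 0.112), hbbe3 at 2265 ± 1167 against 5488 ± 2668 FPKM (adjusted p = 0.0800) and hbbe1.1 at 332.9 against 761.9 FPKM (adjusted p = 0.0502). hbbe3, hbae3 and hbbe1.1 passed the test with the replicate block (0.0081, 0.0127 and 0.0131), without sibling 2 (0.0253, 0.0294 and 0.0373) and without both mutant 1 and sibling 2 (0.0296, 0.0215 and 0.0362). Over all alternatives that called them their adjusted p ran from 0.0081 to 0.0423, 0.0127 to 0.0306 and 0.0131 to 0.0498. Globin means were lowest in mutant 3 (-1.25), mutant 1 (-1.13), sibling 2 (-0.94) and mutant 5 (-0.84), the 4 libraries with the highest means of epidermal markers (0.40, 1.14, 0.55 and 0.23). Across libraries, deviations from the group mean of globin and heme genes had a correlation of -0.88 with those of epidermal markers (exact permutation within groups, p = 2.78e-04). Among 24 genes of the red cell membrane 5 fell and 0 rose (5 and 0 adjusted over the list alone), led by the Rh family genes rhd (11.7 against 32.8 FPKM) and rhag (10.3 against 33.7 FPKM); camera adjusted p = 0.0131, and adjusted p = 0.461 with an estimated correlation. Its library means had a within-group correlation of -0.72 with epidermal markers (p = 0.0213).

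Erythroid transcription factors did not move together. Of 21 tested genes 1 rose, gfi1aa, at 10.6 ± 4.96 against 1.97 ± 1.07 FPKM (SD, n = 5), and 0 fell (1 and 0 adjusted over the list alone). The list's camera direction and mean (0.09) were upward and its median (-0.01) downward, at a camera adjusted p of 0.397. gata1a, used for the sort, was at 53.05 ± 18.2 and 70.7 ± 23.3 FPKM (adjusted p = 0.432). The factors klf1 and nfe2 and the receptor gene epor of this list, at 16.1 and 31.2, 8.13 and 12.8, and 30.1 and 39.1 FPKM, also missed the threshold. klf1 passed it without sibling 2 (adjusted p = 0.0454), without both mutant 1 and sibling 2 (0.0456) and with the replicate block (0.0150), and nfe2 with the block (0.0427). Library means of these factors and of the iron genes had within-group correlations of -0.74 each with epidermal markers (p = 0.0200 and 0.0076). Of 13 genes of iron uptake and storage 0 rose and 2 fell (0 and 2 adjusted over the list alone), among them TFR2, whose call ended without mutant 3 or sibling 4 (0.0533 and 0.0566); the camera adjusted p was 0.167. The iron list was called lower without sibling 2 (0.0230), with it counted as a mutant (0.0036), without both mutant 1 and sibling 2 (0.0331), with the replicate block (0.0237) and with no filter on low values (0.0432). tfr1a, the transferrin receptor, was at 180.3 and 325.8 FPKM (adjusted p = 0.0845) and passed without sibling 2 (0.0212), with it counted as a mutant (0.0275), without both mutant 1 and sibling 2 (0.0309), with array weights (0.0373) and with the replicate block (0.0191).

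Genes of TGF-beta signalling, a pathway with a role in red cell maturation, went both ways. Of 41 tested genes 3 rose and 3 fell (4 and 3 adjusted over the list alone). The ligand tgfb1b was at 21.2 ± 4.75 against 11.1 ± 1.99 FPKM (SD, n = 5), the activin antagonist fsta at 3.12 against 1.09 FPKM and smad3b at 2.27 against 0.96 FPKM. tgfbi, a TGF-beta induced matrix gene, was at 4.04 against 16.5 FPKM, the activin subunit inhbaa at 0.53 against 1.95 FPKM and tgfb3 at 2.14 against 4.64 FPKM. The camera adjusted p was 0.543 (0.0406, called higher, with sibling 2 counted as a mutant), with an upward direction where the median and mean (both -0.04) lay below 0. The call of smad3b ended without mutant 6 (0.0554), without both mutant 1 and sibling 2 (0.0571) and with the replicate block (0.0645). That of tgfb3 ended without mutant 4, 5 or 6 or sibling 4, with no filter, with an equal sum without globin, mitochondrial and rRNA genes or with the replicate block (0.0552 to 0.0625). With sibling 2 counted as a mutant smad3b, tgfb3, tgfb1b, tgfbi and inhbaa were at 0.141, 0.361, 0.126, 0.1745 and 0.0958. Within groups the list's means had a correlation of 0.88 with epidermal markers (p = 0.0088).

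**Figure D2:**
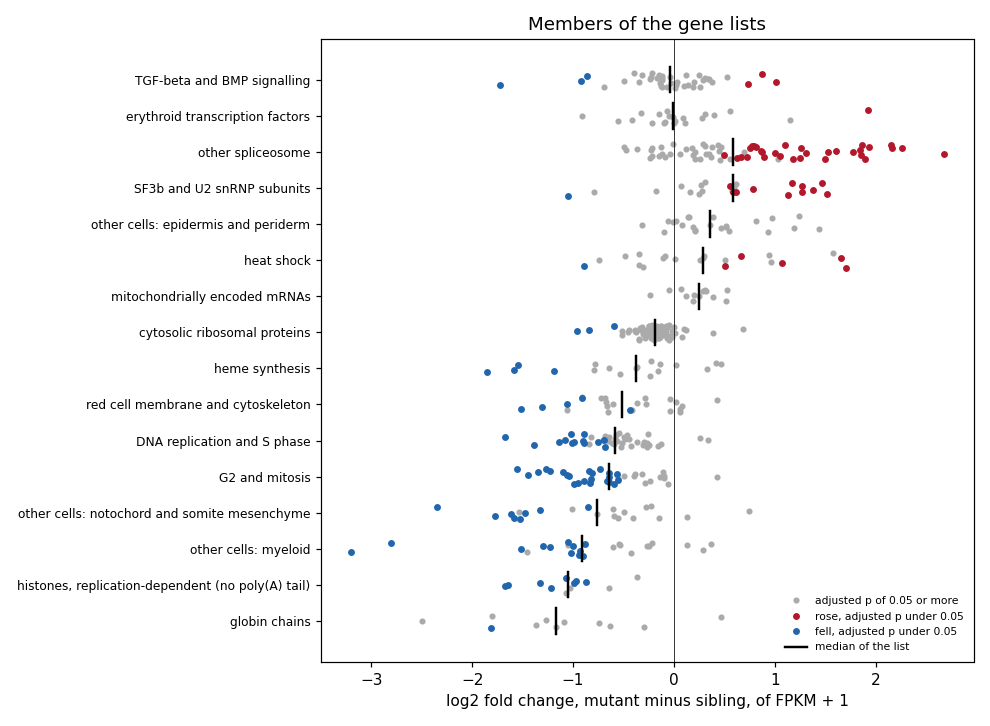
log2 fold change of FPKM + 1, mutant minus sibling, of each tested member of 14 of the 15 lists called by camera and of 2 further lists; colour marks members past an adjusted p of 0.05 and black bars the median. Of 64 wider spliceosome genes 31 rose, and of 37 genes of G2 and mitosis 23 fell.

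Markers of other blood and tissue cells that a sort could hold differed between the groups. Myeloid markers fell in 12 of 24 cases and rose in 0 (14 and 0 adjusted over the list alone), with a median of -0.92; besides mpx and lyz, ptprc, the common leukocyte antigen, was at 3.13 against 8.49 FPKM and mfap4, a macrophage marker, at 12.4 against 34.4 FPKM. The camera adjusted p was 9.28e-07, and adjusted p = 0.445 with an estimated correlation. Markers of notochord and somite mesenchyme fell in 8 of 21 cases and rose in 0 (11 and 1 adjusted over the list alone), led by col1a1a, col1a1b, col1a2 and matn4; camera adjusted p = 8.38e-05, and adjusted p = 0.537 with an estimated correlation. That call ended with sibling 2 counted as a mutant (0.133), with the median at -0.37 from -0.76, and the median was -0.48 with the replicate block and without both mutant 1 and sibling 2. Epidermal markers were higher as a list with 0 of 23 past the test (0 also adjusted over the list alone); cldnb was at 31.3 and 12.96 FPKM and epcam at 64.9 and 29.99 FPKM. That list had a camera adjusted p = 0.0131, and adjusted p = 0.698 with an estimated correlation, and its median of 0.36 was 0.59 without sibling 2. The call ended without mutant 1 or sibling 6, at 0.0729 and 0.0629 (medians of 0.22 and 0.24), and at a mean of at least 5 FPKM (0.0630). cldnb passed the test without mutant 6 (0.0494) or sibling 2 (0.0278), with sibling 2 counted as a mutant (0.0385), without both mutant 1 and sibling 2 (0.0232), with median of ratios scaling (0.0490), with array weights (0.0335) and with the replicate block (0.0061), and epcam without both libraries (0.01) and with the block (0.0215). Within groups, notochord and mesenchyme means had a correlation of 0.84 with epidermal means (p = 0.0063) and myeloid means 0.51 (p = 0.188).

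Among stress and housekeeping lists, 5 of 21 heat shock genes rose and 1 fell (6 and 1 adjusted over the list alone). hsf1, the heat shock transcription factor, was at 15.6 against 4.06 FPKM and the mitochondrial chaperonin genes hspe1 and hspd1 at 11.3 against 2.84 and 128.2 against 60.5 FPKM; camera adjusted p = 0.0157, and adjusted p = 0.630 with an estimated correlation. The list's median of 0.29 was 0.17 without sibling 4 or sibling 6, where the call ended (0.0807 and 0.0715), and 0.51 without sibling 2. Of 77 cytosolic ribosomal protein genes 3 fell, rpl5a, rpl12 and rpl34, and 0 rose (3 and 0 adjusted over the list alone), at a camera adjusted p = 0.0330, and adjusted p = 0.805 with an estimated correlation. The list's median of -0.19 became 0.01 after quantile normalization, -0.12 after median of ratios scaling and -0.0845 without mutant 1, and its call ended in each case (0.983, 0.124 and 0.570). The call also ended without sibling 4 (0.0807), sibling 5 (0.121), sibling 6 (0.102) or both mutant 1 and sibling 2 (0.0547). Its means had a within-group correlation of -0.85 with epidermal markers (p = 0.0083). The call of rpl34 ended after quantile normalization (0.0612). Of 13 mitochondrially encoded mRNAs 0 rose and 0 fell (0 also adjusted over the list alone), mt-co3 being at 1552 and 1084 FPKM; camera adjusted p = 0.0330, and adjusted p = 0.698 with an estimated correlation. That call ended without mutant 4 (0.155, with the median at 0.16 from 0.25), mutant 6 (0.0570), sibling 4 (0.0740), sibling 5 (0.0736) or sibling 6 (0.102), and at a mean of at least 5 FPKM (0.0630).

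Lists of other kinds were not called by camera in the main test, though 4 of them were under some alternatives. In nonsense-mediated decay and the exon junction 3 of 17 rose (eif4a3, casc3 and rnps1) and 3 fell, with a median of -0.01, a mean of 0.03 and an adjusted p of 0.493. The interferon and innate response list had 1 of 17 up and 5 down (adjusted p = 0.180), with il1b and tnfa among those that fell. The unfolded protein and integrated stress response list had 0 of 32 up and 4 down, chac1, atf4a, phgdh and atf4b (adjusted p = 0.212). Autophagy had 1 of 23 up, foxo3b, and 1 down (0.672), and nuclear oxidative phosphorylation 4 of 71 up, including cox7a3, and 3 down, including ndufb4 (0.130). Progenitor genes had 1 of 15 up and 0 down (0.167), skeletal muscle 0 of 22 up and 3 down, including ckma and acta1b (0.163), neural 0 of 21 up and 2 down (0.275), endothelium 0 of 26 up and 3 down, including stab1 and sox18 (0.391), thrombocyte 0 of 6 up and 1 down, plek (0.123), and yolk and liver 1 of 4 up, apoeb, and 0 down (0.124). Lens and eye had 0 of 5 called (0.672), clock and light 0 of 22 (0.834), and pigment and neural crest 0 of 6 up and 1 down (0.852), with a median of -0.06 and an upward camera direction. Adjusted over the list alone, the counts up and down in these lists were equal to those over all genes except for interferon (1 and 6), autophagy (1 and 0), neural (0 and 0) and pigment (1 and 1). Thrombocyte markers were called lower without sibling 2 (0.0391), with it counted as a mutant (0.0280), without both mutant 1 and sibling 2 (0.0356), with the replicate block (0.0376) and with no filter (0.0445), and muscle markers without sibling 6 (0.0069) and with no filter (0.0478). Oxidative phosphorylation was called higher without mutant 1 (0.0202) or sibling 6 (0.0426), and yolk and liver without sibling 2 (0.0259), with it counted as a mutant (0.0165) and without both mutant 1 and sibling 2 (0.0288). Fry also called thrombocyte markers lower (fry adjusted p = 0.0060) and yolk and liver markers higher (0.0315). The call of sox18 ended with the replicate block (0.0521). Within groups, epidermal means had correlations of 0.94 with lens and eye, 0.85 with pigment, 0.83 with muscle, 0.81 with the unfolded protein response, 0.71 with neural, 0.70 with interferon, 0.68 with yolk and -0.67 with oxidative phosphorylation (p of 0.0406 or less, not adjusted). Over all 34 lists camera called 15 with the preset correlation (6 higher, 9 lower) and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05, and fry called 11.

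**Figure D3:**
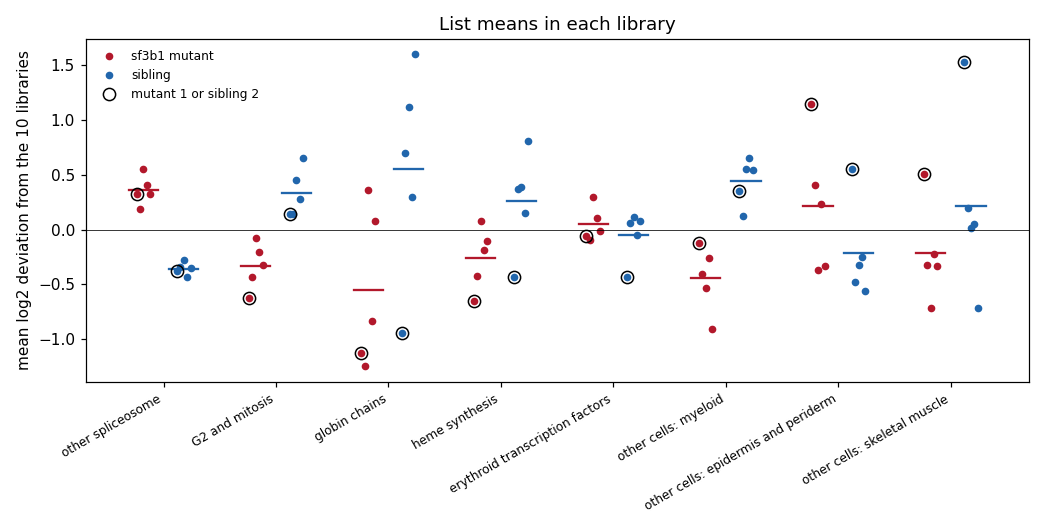
Mean log2 deviation of the members of 8 lists in each library (red, 5 mutants; blue, 5 siblings; bars, group means; rings, mutant 1 and sibling 2). Spliceosome means separated the groups, while mutant 1 and sibling 2 had the highest epidermal means, 1.14 and 0.55.

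Changed genes were not concentrated on the chromosome of sf3b1. On chromosome 9, without sf3b1 itself, 73 of 457 tested genes were called (16.0%), against 1788 of 12518 on the other chromosomes (14.3%), an odds ratio of 1.14 with a one-sided Fisher exact p of 0.172. Within 10 Mb of sf3b1, 30 of 180 other genes were called, with a one-sided Fisher exact p of 0.209. These counts do not exclude linkage for single genes such as f5.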

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

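The tests on myeloid, globin and heme genes and the comparison of spliceosome genes with erythroid transcription factors were chosen after the results were seen. The tests of scaling, of linkage and of other splits were written before.

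A single library lay far from the other 4 of its group in 16 of 292 groups examined (5.5%, where chance gives about 1 in 20), by a gap above 0.71 of the group's range. Mutant 1 was the lowest mutant for cpn1 (ENSDARG00000096720, 12.7 FPKM against 21.8 to 23.5) and ppox (11.1 against 17.9 to 21.1), and the highest for ftr34 (34.4 against 7.17 to 11.4), epcam (156.2 against 38.1 to 49.8) and hsf1 (23.0 against 13.2 to 14.3). Mutant 1 also had the most rows above 0, 21397 against 20247 to 20580 in the other mutants. Sibling 2 was the highest sibling for apoeb (48.1 FPKM against 24.4 to 26.2), and for the list means of epidermal markers (0.55 against -0.56 to -0.25) and of yolk and liver markers (0.44 against -0.63 to -0.40). Sibling 6 was the lowest sibling for ftr34 (0.15 FPKM against 1.203 to 1.45), and sibling 5 for snapc4 (2.44 against 4.15 to 4.78) and hsf1 (2.46 against 4.08 to 4.91). Sibling 4 was the highest for tgfb1b (14.6 FPKM against 9.86 to 10.3), mutant 5 for il1b (9.57 against 4.32 to 5.12) and mutant 4 for sf3b4 (81.4 against 59.2 to 64.9). Sibling 3 had the lowest mean of the nonsense-mediated decay list (-0.12 against 0.01 to 0.02).

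Of 64 wider spliceosome genes 31 rose in mutants (adjusted p = 0.0754 with an estimated correlation). Scaling between libraries is argued against: over 3 other scalings the median of the wider spliceosome list was 0.65 at the lowest. Linkage to the mutated gene is argued against, because 1 of 42 rising members (2.4%) lies on chromosome 9. A purer erythroid sort is not settled. The wider spliceosome list rose by 0.63 more than erythroid transcription factors (exact permutation p = 0.0079), but several of those factors are also used by other blood cells. The rise may be a response of the cells to low sf3b1. That hypothesis was not tested, and these data cannot separate it from other differences between mutant and sibling embryos.

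Of 24 myeloid markers 12 fell in mutants (adjusted p = 0.445 with an estimated correlation). An equal loss of every other cell type from the mutant sort is argued against, since epidermal markers moved away from myeloid markers by 1.32 on the log2 scale (exact permutation p = 0.0159; 1.17 to 1.53 with each library left out in turn, p of 0.0238 or less). That rests on the epidermal list, of which 0 of 23 passed the test, while notochord and mesenchyme (8 of 21 fell), thrombocyte and muscle markers had medians of -0.76, -0.49 and -0.38, so a loss of several cell types is not excluded. Fewer myeloid cells and lower expression within them both stay open.

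Globin and heme genes had a median of -0.65 over 29 genes, of which 1 globin row and 4 heme genes fell, and both lists had adjusted p = 0.698 with an estimated correlation. Epidermal cells, or other cells that come with them, in a share that differs between libraries may account for part of this, although the sort for gata1 works against it: deviations from the group mean had a correlation of -0.88 with those of epidermal markers (-0.94 to -0.82 with each library left out), and the group difference of library means went from -0.74 (SE 0.35, p = 0.0672) to -0.36 (SE 0.20, p = 0.114) with the epidermal mean in the model. Globin and heme means lay lower than those of erythroid transcription factors by 0.83 (-0.83, exact permutation p = 0.0238). This does not settle whether dilution is the whole cause, as several of those factors are also used by other blood cells. In addition gata1a, klf1, nfe2 and the receptor gene epor, which that list also holds, had negative log2 fold changes. Mutant 1 and sibling 2 are argued against as the whole cause, because the median was -0.76 without them. A delay of maturation in mutant cells may remain, and was not tested.

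Chance is argued against for the number of changed genes, but 100 splits do not exclude it. Among 100 of the 126 possible splits of the 10 libraries, 1, the real one with 1864 genes, gave as many. The highest of the others gave 11. Each other split put mutants and siblings together on both sides, which adds the genotype difference to the spread within groups. The 11 genes therefore do not measure how many calls chance alone would give. Chance is not argued against for the number of called lists. Of 100 splits 25 gave at least 15 lists, and the highest of the others gave 22. The 5 splits with the most lists all put mutant 1 and sibling 2 on the same side, which points to a structure of the samples apart from genotype.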

How the results depend on the processing

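The alternatives that leave out mutant 1 and sibling 2 together, leave out small noncoding RNA rows or permute library means were chosen after seeing the data. sf3b1 stayed lower and past the threshold under all alternatives run (log2 fold change -1.09 to -0.86, adjusted p 1.67e-04 to 0.0479), and the odds ratio of its chromosome stayed between 1.01 and 1.21 (p 0.0967 to 0.505). Leaving out 1 library gave 1282 to 1950 changed genes (524 to 735 higher, 741 to 1238 lower), 11 to 19 lists, log2 fold changes of sf3b1 of -1.09 to -0.99 and odds ratios of 1.04 to 1.21. Counting sibling 2 as a mutant gave 761 genes (300 higher, 461 lower), and the cause of the lower count was not tested. The values of sibling 2 argue against its mutant tag. Its sf3b1 level was 41.0 FPKM, against 16.0 to 21.3 FPKM in mutants. Its wider spliceosome mean was -0.38, against 0.19 to 0.55 in mutants and -0.43 to -0.28 in the other siblings. A mean of at least 5 FPKM gave 755 lower genes from fewer genes tested. Without both mutant 1 and sibling 2, 2016 genes changed (758 higher, 1258 lower) and 18 lists were called. Lists called numbered 0 with an estimated correlation, 11 with fry and 7 by exact permutation of library means. Both splicing lists and the G2, replication, histone and myeloid lists were called by fry and by permutation. The red cell membrane and the notochord and mesenchyme lists were called by fry but not by permutation. So were the thrombocyte and the yolk and liver lists, which camera did not call in the main test. The globin, heme, ribosomal protein, heat shock, mitochondrial mRNA and epidermal lists were called by neither. The labels do not say whether replicate numbers pair the libraries. Same-number correlations of deviations were -0.03, 0.09, 0.10 and 0.15 for numbers 3 to 6, so not every one was over 0.1. The numbers were therefore not taken to pair the libraries. Mutants 5 and 6 correlated best with their own number and mutants 3 and 4 did not. The highest correlation was 0.30, between mutant 1 and sibling 2, which have different numbers and stood apart together on the second principal component. A shared origin of these 2 is not excluded, and no block with them as a pair was run. The replicate block, run on numbers 3 to 6 only, gave 1944 changed genes and 17 lists, with sf3b1 at -1.02 and an odds ratio of 1.07. It therefore also left out mutant 1 and sibling 2, so its differences from the main test are not those of the block alone. Leaving out both without a block gave 2016 genes and 18 lists, with sf3b1 at -1.02. Besides those printed with the results, the block changed no call of a named gene or list.

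Lists that were not called changed camera direction as follows, with medians and the cause not tested. With sibling 2 as a mutant these were erythroid factors -0.14, oxidative phosphorylation -0.017, muscle 0.26, neural -0.085, endothelium 0.0097 and clock -0.0070. Erythroid factors turned without sibling 2 (-0.13; -0.13 to 0.044 over all libraries left out in turn), endothelium with the replicate block (-0.050), pigment without a filter (-0.087) and without mutant 3 (-0.11), sibling 3 (-0.16) or sibling 6 (-0.036; -0.16 to 0.099), and clock at a mean of at least 5 FPKM (0.018) and without mutant 3 (0.059), mutant 6 (-0.041) or sibling 2 (-0.064; -0.30 to 0.059). For lists 716 values kept their side of the threshold, 26 lost it, 21 gained it and 16 turned. For named genes 2269 values kept their side of the threshold, 70 lost it, 38 gained it and 0 changed sign. Absolute depth is unknown, which limits low genes.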

Other observations

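The stretch of chromosome 25 was chosen after its values were seen, and the test of locus length before. Chromosome 25 had the most changed genes for its size, 102 of 430 (23.7%, adjusted p = 4.30e-06), of which 80 fell. Between 34 and 36 Mb, where several replication-dependent histone rows lie, 61 of 113 genes changed, 54 of them downward, while on the rest of the chromosome 41 of 317 did (12.9%), against 14.0% on other chromosomes. Of the 113 genes 19 carry a histone symbol or stand in the histone list, and 13 of these fell; many of the others carry clone names, so the number of histone rows is a lower bound. Near-identical copies share reads there, so the rows are not independent.

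Longer genes tended to be lower in mutants. Across 12738 genes, which are not independent replicates, Spearman's rho between log2 fold change and locus length was -0.07. With genes ranked by length into 5 equal groups, in the longest (median 86.4 kb) 57 genes rose and 210 fell, against 177 and 295 in the shortest (median 3.52 kb) and 206 and 156 in the next (9.22 kb). A splicing load that grows with length may play a part, but the rho of -0.07 lies between the bounds set beforehand and leaves that open.

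Among rows of spliceosomal small nuclear RNAs, whose copies share reads, 3 of 4 U4 rows rose. Of the others, 0 of 32 U1, 0 of 5 U2, 0 of 5 U5, 0 of 2 U6, 0 of 2 U11 and 0 of 1 U12 rows passed the test. Their median log2 fold changes were all above 0, at 0.77, 0.46, 0.59, 1.62, 1.26 and 2.09, against 2.23 for U4. A rise particular to U4 is therefore not shown. The calls of 2 of the U4 rows ended under several alternatives, and the U4 rows were described after their values were seen.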
